A study of Homo sapiens with 5 samples.

How the data were processed

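MDA-MB-231 is an established human breast cancer cell line that lacks the estrogen receptor and is classed as basal. Fluvastatin is a statin, a cholesterol-lowering drug that blocks the mevalonate pathway. Per the labels, cultures received water as a mock control or 10 µM fluvastatin for 24 h, and total RNA was converted to biotin-labelled cRNA and hybridised to Illumina bead arrays. The labels list 3 control samples and 2 fluvastatin samples. The treatment text of the fluvastatin samples repeats the wording for the mock control, so the groups were taken from the sample titles and characteristics. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples.

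The deposited raw table holds 1 intensity per probe and sample for 47231 probes, which the authors gave without background subtraction or normalization, as far as the values show. Each deposited intensity is followed by a detection p-value, per the file headers. The authors' processed table holds log2 values whose columns differ by at most 0.0166 at the same rank (median 0.00104) and have rank correlation 1 with the raw signal of the same sample. Quantile normalization gives columns of nearly equal distribution. Its package is not stated; R 3.1.0 is named in the submitters' processing notes. The median of each column of the authors' log2 table was 6.23 to 3 digits. Every per-sample column was mapped to a sample, and 0 such columns were left unused.

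Control replicate 2 is not an independent measurement in these files. In 47231 of 47231 probes its intensity equalled the arithmetic mean of control replicates 1 and 3 to within 1e-06, and so did its detection p-value. A second decimal was needed by 50.1% of its intensities and by 0% of those of every other sample. The test design written before the data were examined used all 5 columns. It was changed once this was found and before any test had been run: the main fit used the 4 independent arrays, control replicates 1 and 3 and fluvastatin replicates 1 and 2. The fit on all 5 columns, as first written, is reported beside it.

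Intensities were processed with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, corrects it by normexp, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 21986. Groups were compared by limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the probes kept and an adjusted p under 0.05 as the threshold. A further count required an absolute log2 fold change of at least 1. The fit had 2 residual degrees of freedom and 3.72 prior degrees of freedom. Errors of log2 fold changes are moderated standard errors.

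Gene symbols came from the platform annotation, which was checked through gene identifiers against a RefSeq gene table of assembly GRCh38.p14 (0 symbols changed). Of all probes, 30113 had 1 symbol, 8 had several and 17110 had none. Of the probes kept, 16542 had 1 symbol, 3 had several and 5441 had none. Unnamed probes are not evidence that a gene is absent from the array. Each of 12080 genes was represented by its kept probe with the highest mean log2 value. Of 404 genes with several probes past the threshold, 5 had probes of opposite sign. The files name no genome build, so no positions are given.

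Lists of genes (38) were fixed before the data were examined and tested with camera of limma, a competitive two-sided test, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Members past the threshold were counted over all probes kept and also adjusted over the list alone. The rule for named genes, also fixed beforehand, took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap. Symbols that are LOC numbers or other provisional names were left out of this ranking. It also took up to 4 members per list with the smallest p. The rule also fixed 1 gene in advance that is not analysed here, and 2 of the 38 lists are not described here. A probe above background on no array of a group was given as a bound. The bound sets the brighter group's mean against the mean, in the dimmer group, of the lowest signal among detected probes or the probe's own, whichever was higher on each array.

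The steps were tested on simulated data. Among 21986 simulated probes compared as 2 against 2 arrays, changes of 1 on the log2 scale were recovered in 12.0% of 50 probes, changes of 2 in 86.0%, changes of 3 in 98.0% and changes of 4 in 100%. Of 161 calls in all, 13 were false. With 30% of probes changed, 3.80% of 2997 calls were false. A shift of -0.50 given to the list of G2/M genes was called by camera with an adjusted p of 3.16e-20, and 0 other lists were called. Noise was drawn independently for each simulated probe. The run therefore does not show how often lists of genes that vary together are falsely called.

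Alternatives fixed before the data were examined were no background correction, an offset of 50, cyclic loess or median scaling in place of quantile normalization, no filter, a stricter filter, and the authors' values. Others were eBayes with trend and robust, array weights, the mean of all probes of a gene, camera with an estimated correlation, the test fry, and leaving out each array in turn. The authors' values with all 5 columns were added after seeing the data. The files give no slides, so a slide block was not run. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.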

Results

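Gene expression was measured in MDA-MB-231 breast cancer cells after 24 h with 10 µM fluvastatin or with water. Control replicate 2 was in every probe the mean of the other control columns, so 2 independent control arrays were compared with 2 fluvastatin arrays. Of 47231 probes, 21761 (46.1%) were detected in control replicate 1 and 20295 (43.0%) in control replicate 3. The fluvastatin arrays had 22154 (46.9%) in replicate 1 and 21200 (44.9%) in replicate 2. Median intensities were 74.0 and 72.7 in the controls and 74.2 and 81.7 with fluvastatin. The controls correlated with r = 0.994 across the probes kept and the fluvastatin arrays with r = 0.982, and genes are not independent replicates. Between the controls 0.337% of probes lay at least 2-fold apart, and between the fluvastatin arrays 2.77%.

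The comparison asks which transcripts differ between fluvastatin-treated and untreated malignant breast cells. Rises and falls are ranked by the rule for named genes, which leaves out provisional symbols. The largest rise was that of RHOB, whose mean log2 intensity was 6.19 ± 0.20 in controls and 10.60 ± 0.42 with fluvastatin (SD, n = 2 each), a log2 fold change of 4.40 ± 0.25 (SE). The largest fall was that of CCN2 (CTGF), a matricellular protein and a standard target of the coactivators YAP and TAZ, from 12.21 ± 0.0026 to 7.29 ± 0.15, a log2 fold change of -4.92 ± 0.16. BMF, a pro-apoptotic BH3-only protein, rose by 3.68 ± 0.17 and KLF2, a transcription factor that statins induce in endothelium, rose by 3.04 ± 0.17. The Wnt antagonist DKK1 (-4.19 ± 0.21), ANKRD1 (-4.07 ± 0.31) and CCN1 (-3.82 ± 0.16) fell with CCN2.

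The other genes with the largest rises were AKR1C2 (log2 fold change 3.61), AHNAK2 (3.58), complement factor CFB (3.31), the leucine zipper protein gene TSC22D3 (3.31), CALHM3 (2.97), FAXDC2 (2.95) and the tight junction gene CLDN7 (2.95). The other large falls were RIMS2 (-3.44), the cytokine IL11 (-3.29), the natriuretic peptide gene NPPB (-3.19), DMBT1 (-3.14), MARCHF4 (-2.97) and the amino acid transporter SLC7A2 (-2.68). The adjusted p of the 20 named genes ran from 0.00346 for CCN2 to 0.0239 for AKR1C2. AKR1C2 is uncertain: its second probe, near background, gave -0.42 (adjusted p = 0.110), and its level differed between the fluvastatin arrays (10.13 and 7.95). Without a filter on dim probes its adjusted p was 0.0672. Other probes of BMF gave 4.20 (adjusted p = 0.00396) and, near background, 0.70 (adjusted p = 0.0638). RIMS2 and NPPB were also dim with fluvastatin (mean log2 intensities 5.01 and 4.77). So were BMF (5.39), CALHM3 (5.34) and FAXDC2 (5.47) in controls. The sizes of such changes depend on the background correction and the offset. A second, dim probe of FAXDC2 gave 1.28.

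**Figure D1:**
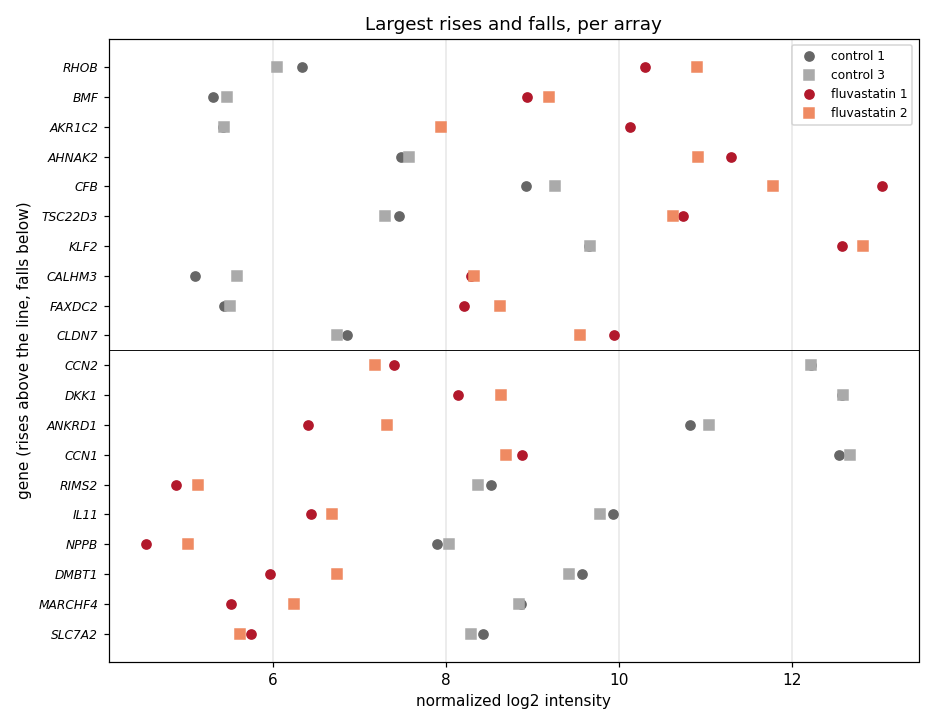
Normalized log2 intensity of the genes with the 10 largest rises and 10 largest falls on each of the 4 independent arrays, 1 point per array. Genes were chosen so that both fluvastatin arrays lie beyond both control arrays, leaving out provisional symbols. Log2 fold changes run from 4.40 for RHOB to -4.92 for CCN2.

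Of the 21986 probes kept, 3722 (16.9%) changed, 1899 of them higher and 1823 lower with fluvastatin. The near-even split depends on the scaling: median scaling gave 3353 higher and 961 lower (77.7% higher). That scaling aligned the median of all 47231 probes, of which 43.0% to 46.9% were detected per array. It thus aligned the arrays on a value near background. Its fit also had infinite prior degrees of freedom, so all probes shared 1 variance. At least 2-fold changes were found for 1761 probes, 922 higher and 839 lower, but for 780 without background correction, 1084 with an offset of 50, 841 with the authors' values, 858 with those of all 5 columns and 433 to 2871 leaving out 1 array. By gene, 2431 of 12080 (20.1%) changed, 1265 higher and 1166 lower. The fit to all 5 deposited columns called 8991 probes, including each of the 3722, but counts the mean of the other controls as an independent control. Without control replicate 1 the count was 468, without control replicate 3 it was 433 and without fluvastatin replicate 2 it was 7046.

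Of the 38 gene lists, 13 passed the camera test, 8 higher and 5 lower, and 0 passed with an estimated correlation. That mode rests on 2 residual degrees of freedom, so a list that it did not pass is left undecided. For the G1/S list the estimate was 0.00855, below the preset 0.01, yet camera p went from 7.46e-15 to 0.0156. The estimate was far above the preset for the hypoxia (0.682), NF-kB (0.467), matrix metalloproteinase (0.335), interferon (0.261) and cholesterol (0.253) lists. Camera p-values of these lists with the preset therefore rest on a correlation below the estimate. Among the other lists that passed, the highest estimate was 0.0408, for autophagy and lysosome genes. Of the 13, 1 is not described here. The fry test, which asks whether genes move on balance in a direction, passed 12 lists, 8 of them among the 13. Passing fry but not camera were the SRF and MRTF targets (fry adjusted p = 0.0108), nitric oxide and arginine metabolism (0.0152), CDK inhibitors (0.0167) and KLF2-associated genes (0.0361). Passing camera but not fry were the cholesterol (0.0629), interferon (0.0821), hypoxia (0.201), matrix metalloproteinase (0.201) and NF-kB (0.463) lists. Values per list are log2 medians over the measured members.

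**Figure D2:**
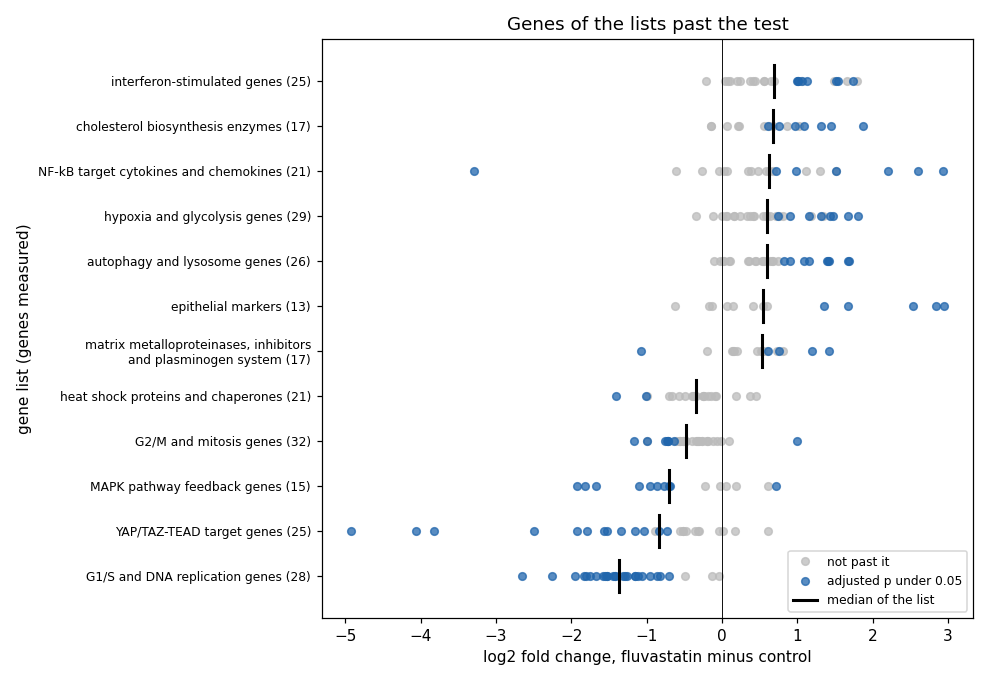
Log2 fold change of each measured gene in 12 of the 13 lists that passed the camera test (the other is not described here), with the median of each list as a bar and the number of genes in parentheses. The medians run from -1.37 for the G1/S and DNA replication genes to 0.70 for the interferon-stimulated genes.

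Enzymes of cholesterol biosynthesis rose: 7 of 17 measured members rose, 0 fell and 10 did not pass, and adjusted over the list alone 12 rose. HMGCS1, which makes HMG-CoA, rose by 1.87 ± 0.16, LSS by 1.44, the mevalonate kinase MVK by 1.09 and SQLE by 0.97. The list median was 0.67 (adjusted p = 0.000622; adjusted p = 0.639 with an estimated correlation; adjusted p = 0.0629 by fry). The list of sterol uptake, trafficking and sensing genes did not pass (adjusted p = 0.383), with INSIG1 higher by 1.02 and TMEM97 at -1.01 as its changed members of 12. Adjusted over the list alone, 4 rose and 1 fell. Fatty acid synthesis and desaturation genes did not pass (adjusted p = 0.904), with 2 of 17 higher, among them the desaturase SCD (1.49), and 2 lower. LXR targets (adjusted p = 0.498) had 1 of 8 higher, SCD, and 1 lower, MYLIP (-1.32). Prenyltransferases and prenylation-processing enzymes (adjusted p = 0.837) had 2 of 14 higher, RABGGTA (1.25) and DHDDS (0.81), and 2 lower, PDSS1 (-1.35) and RABGGTB (-0.64). Adjusted over the list alone, the fatty acid list had 3 higher and 3 lower, the LXR list 3 and 1, and the prenylation list 2 and 3.

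Targets of YAP/TAZ and TEAD fell, with 13 of 25 members lower, 0 higher and 12 not past the test. Adjusted over the list alone, 17 fell and 1 rose. CCN2, CCN1, ANKRD1 and FJX1 had the smallest p. The median was -0.83 (adjusted p = 5.6e-07; adjusted p = 0.479 with an estimated correlation), and -0.50 without background correction. Feedback genes of the MAPK pathway fell, with 9 of 15 lower and 1 higher, and 9 and 2 adjusted over the list alone. EPHA2 (-1.83), FOSL1 (-1.92), the cyclin gene CCND1 (-1.68) and the phosphatase gene DUSP6 (-0.96) were among them. Their median was -0.70 (camera adjusted p = 0.0117, and 0.523 with an estimated correlation). It was -0.45 with median scaling, or -0.64 relative to the shift of the probes kept there. The call was lost without fluvastatin replicate 1 and with the mean of all probes of a gene (camera adjusted p = 0.0733).

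Cytoskeletal targets of SRF and MRTF did not pass camera (adjusted p = 0.468), with 3 of 20 higher and 3 lower, and 4 and 8 adjusted over the list alone. FILIP1L was at 1.05, CNN2 at -1.02 and SRF itself at -0.86. The KLF2-associated genes that statins induce in endothelium did not pass as a list (adjusted p = 0.328). KLF2, KLF6 (1.63) and HMOX1 (1.90) were among 5 of 12 higher, while EDN1 (-2.22) and THBS1 (-1.15) were the 2 lower. There were 6 higher and 3 lower when adjusted over the list alone. Immediate early genes did not pass (adjusted p = 0.571), with 2 of 13 higher, among them ATF3 (0.93), and 3 lower, FOSL1, DUSP6 and MYC (-0.77), and 6 and 3 adjusted over the list alone.

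Genes of the G1/S transition and DNA replication fell: 25 of 28 measured members fell, 0 rose and 3 did not pass, and 25 fell adjusted over the list alone. MCM10 fell by 2.66 ± 0.15, UHRF1 by 1.95, the phosphatase CDC25A by 2.26 and cyclin E1 (CCNE1) by 1.81. The median of -1.37 was -1.31 in fluvastatin replicate 1 and -1.41 in replicate 2 (adjusted p = 2.83e-13; adjusted p = 0.479 with an estimated correlation). G2/M and mitosis genes fell as well, with 7 of 32 lower, 1 higher and 24 not past the test, and 14 lower and 1 higher adjusted over the list alone. PLK1 (-1.17), TOP2A (-0.76) and CDC20 (-0.73) fell and CDC25B rose (0.99), with a list median of -0.48 (camera adjusted p = 0.000125, and 0.523 with an estimated correlation). The G2/M median was -0.27 with median scaling, or -0.46 relative to the shift of the probes kept there.

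CDK inhibitors did not pass as a list (adjusted p = 0.0865; past the threshold in 2 of 15 other settings, adjusted p = 0.0298 to 0.191), though 2 of 5 rose, CDKN1C (1.76) and CDKN1A (0.90), and 3 adjusted over the list alone. The p53 targets did not pass (adjusted p = 0.345), with 5 of 18 higher, among them GDF15 (2.38) and TP53INP1 (1.68), and 3 lower, among them AEN (-2.39) and TIGAR (-1.40). With p adjusted over the list alone, 6 were higher and 3 lower. Apoptosis regulators did not pass (adjusted p = 0.979): BMF rose and was 1 of 2 higher among 24, and BCL2 (-1.95), BCL2L1 (-1.28) and CASP2 (-0.83) were among 4 lower. Adjusted over the list alone, 3 were higher and 5 lower. Replication-dependent histones did not pass (adjusted p = 0.712; past the threshold in 1 of 15 other settings, adjusted p = 0.0337 to 0.846), with 1 of 10 higher, H2BC5 (0.99), and 2 higher and 1 lower adjusted over the list alone. Their median was -0.33 in fluvastatin replicate 1 and 0.52 in replicate 2.

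Interferon-stimulated genes rose, with 8 of 25 members higher, 0 lower and 17 not past the test, and 10 higher adjusted over the list alone. IRF9 rose by 1.74, IFI27 by 1.52, IRF7 by 1.06 and MX1 by 1.12. The median of 0.70 (adjusted p = 9.99e-05; adjusted p = 0.639 with an estimated correlation) was 1.08 in fluvastatin replicate 1 and 0.27 in replicate 2. Hypoxia and glycolysis genes rose, with 8 of 29 higher, 0 lower and 10 higher adjusted over the list alone. SLC2A3 rose by 1.43, NDRG1 by 1.80, BNIP3L by 1.31 and PFKFB4 by 1.47. Their median of 0.60 (adjusted p = 0.00054; adjusted p = 0.729 with an estimated correlation) was 0.92 in replicate 1 and 0.35 in replicate 2.

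Cytokines and chemokines under NF-kB rose as a list, with 6 of 21 higher, 1 lower and 14 not past the test, and 9 higher and 2 lower adjusted over the list alone. IL1A rose by 2.60, SOD2 by 1.51 and IL1B by 2.93, while IL11 fell. The list median of 0.62 (adjusted p = 0.0357; adjusted p = 0.729 with an estimated correlation) was 0.91 in fluvastatin replicate 1 and 0.40 in replicate 2. Without fluvastatin replicate 1 the adjusted p was 0.101, and with all 5 columns it was 0.0537.

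**Figure D3:**
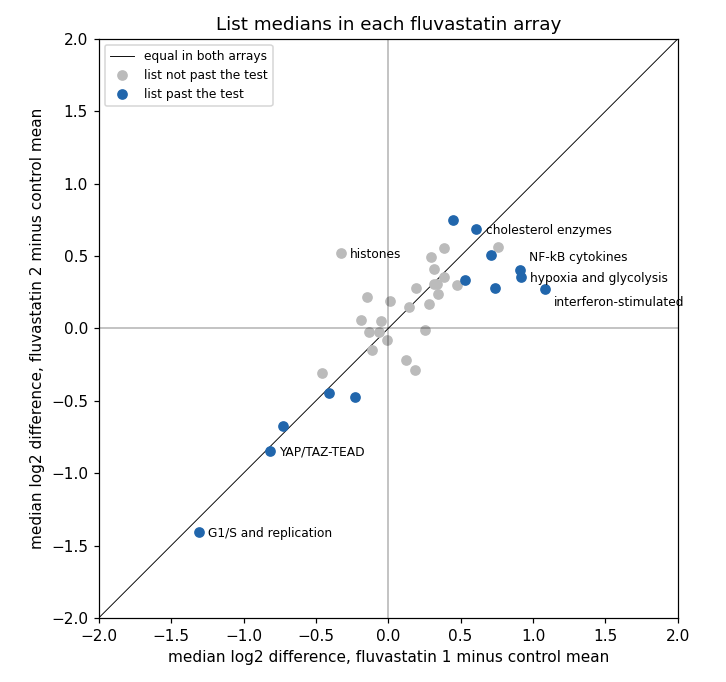
Median log2 difference from the control mean of each of the 38 gene lists in fluvastatin replicate 1 (horizontal) and replicate 2 (vertical), 1 point per list, with the line of equal values. Interferon-stimulated genes lie at 1.08 and 0.27, and G1/S and DNA replication genes at -1.31 and -1.41.

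Epithelial markers rose, with 5 of 13 members higher, 0 lower and 8 not past the test. There were 6 higher and 1 lower when adjusted over the list alone. CLDN7, the transcription factor gene ELF3 (2.84), the mucin gene MUC1 (2.53) and CD24 (1.68) led. The median was 0.55 (adjusted p = 0.0111; adjusted p = 0.523 with an estimated correlation), but 0.13 without a filter on dim probes and 0.37 without background correction, where the list still passed (adjusted p = 0.0132 and 0.00745). Mesenchymal markers did not pass (adjusted p = 0.564): N-cadherin (CDH2) fell by 1.67, the only fall among 10, and 2 were higher. These were FN1, not above background in controls and at least 2.16-fold higher, and FOXC2, at least 1.37-fold higher. With p adjusted over the list alone, 2 were higher and 1 lower. Basal and luminal lineage markers did not pass (adjusted p = 0.894), with 0 of 6 changed, and 3 higher and 2 lower adjusted over the list alone. GATA3 was at -0.82 (adjusted p = 0.0575).

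Matrix metalloproteinases, their inhibitors and the plasminogen system rose as a list, with 4 of 17 higher and 1 lower, and 4 and 1 adjusted over the list alone. MMP11 (1.20), PLAT (0.75) and ADAM17 (1.42) rose, while urokinase (PLAU) fell by 1.08. The median of 0.53 (adjusted p = 0.0357; adjusted p = 0.729 with an estimated correlation) was 0.74 in fluvastatin replicate 1 and 0.28 in replicate 2. It was 0.18 without a filter on dim probes and 0.34 without background correction. Its call was lost in 5 of 15 other settings, among them without control replicate 3 (adjusted p = 0.0512) and without fluvastatin replicate 1 (adjusted p = 0.0893). Extracellular matrix and TGF-beta targets did not pass (adjusted p = 0.737), with 5 of 20 higher, among them TNC (1.13), and 6 lower, among them CCN2 and THBS1. Adjusted over the list alone, 7 were higher and 7 lower. Integrins, CD44 and focal adhesion genes did not pass (adjusted p = 0.250), with 3 of 25 higher, ITGB4 (1.44), ITGA1 (1.49) and ITGA5 (0.74), and 3 adjusted over the list alone.

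Autophagy and lysosome genes rose, with 9 of 26 higher, 0 lower and 17 not past the test, and 16 higher adjusted over the list alone. Cathepsin D (CTSD) rose by 1.67, NEU1 by 1.40, the autophagy receptor SQSTM1 by 1.42 and CTSB by 1.15, and the median was 0.60 (adjusted p = 1.05e-05; adjusted p = 0.523 with an estimated correlation). The median was 0.71 in fluvastatin replicate 1 and 0.51 in replicate 2. Heat shock proteins and chaperones fell as a list (median -0.35, camera adjusted p = 0.0357, and 0.523 with an estimated correlation). The median was -0.12 with median scaling, or -0.31 relative to the shift of the probes kept there. Just HSPH1 (-1.01) and HSPA4 (-1.40) of 21 passed singly, as 2 did adjusted over the list alone. The call was lost without fluvastatin replicate 2 (adjusted p = 0.0671) and with all 5 columns (adjusted p = 0.0537).

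The integrated stress and unfolded protein response did not pass (adjusted p = 0.296), with 6 of 21 higher, among them DDIT3 (1.27) and ASNS (1.00), and 4 lower, among them PSAT1 (-1.36) and SDF2L1 (-1.07). There were 9 higher and 4 lower when adjusted over the list alone. Antioxidant and NRF2 targets (adjusted p = 0.0818) passed in 7 of 15 other settings (adjusted p = 0.0123 to 0.146), among them the authors' values (0.0394), and had 3 of 27 higher, HMOX1 (1.90), SOD2 and CAT (0.83), and 1 lower, SLC7A11 (-0.96). The iron list (adjusted p = 0.581) had 3 of 17 higher, HMOX1, LCN2 (1.02) and STEAP3 (0.80), and 2 lower, among them SLC39A8 (-1.37). For both of these, adjusted over the list alone, 3 were higher, and 1 and 3 were lower in that order. The list of nitric oxide and arginine metabolism (adjusted p = 0.156) had 2 of 14 higher, DDAH2 (1.70) and ASS1 (1.24, chosen after its value was seen), and 3 lower, among them SLC7A2 and GCH1 (-0.94). With p adjusted over the list alone, 2 were higher and 5 lower. Metallothioneins (adjusted p = 0.887) had 1 of 8 higher, MT1F (0.93), and 2 lower, MT1G (-0.95) and MT1E (-0.63), and 2 and 2 adjusted over the list alone. Oxidative phosphorylation (adjusted p = 0.837) had 1 of 25 higher, SDHC (0.78), and 0 adjusted over the list alone. Ribosomal proteins (adjusted p = 0.811) had 0 of 27 changed either way.

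Markers of other cell types gave no call. Of the blood and immune markers 5 of 16 were measured and 0 changed (list adjusted p = 0.887), with CD14 at -0.61 and LYZ at -0.26. Of the fibroblast and endothelial markers 4 of 16 were measured and 0 changed (list adjusted p = 0.361), with PECAM1 at 1.19 (adjusted p = 0.0735). Both lists had 0 members past the threshold adjusted over the list alone.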

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

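Of these alternatives, only the authors' values with all 5 columns were chosen after the data were seen. Probes changed numbered 3722; all 5 deposited columns gave 8991, the authors' values with all 5 columns 8945, and leaving out 1 array 433 to 7046. At least 2-fold changes numbered 1761; the count was 780 without background correction, 1084 with an offset of 50, 841 with the authors' values, 858 with those of all 5 columns, and 433 to 2871 leaving out 1 array. Without background correction or with a larger offset, fold changes shrink by construction, and a derived column lowers the residual spread. With 1 array left in a group, the residual spread comes from the other group, and that array is assumed to vary like it. The median residual SD was 0.18 and 0.184 from the fluvastatin pair (without control replicate 1 or 3). From the control pair it was 0.0898 and 0.0907 (without fluvastatin replicate 1 or 2). The main fit assumes equal spread in both groups, although the fluvastatin pair varied more. How far this spread set the counts, and the cause of the other differences, was not tested. Median scaling moved the median of the probes kept by 0.19 and gave 77.7% of calls higher, against 51.0%. Relative to that shift the cholesterol list stood at 0.70. Under that scaling the medians of 5 of the 38 lists changed sign, none of them past the test, among them extracellular matrix, metallothioneins, oxidative phosphorylation and ribosomal proteins.

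The cholesterol list kept its direction in all alternatives run and its call in 15 of 15 that changed values or arrays, but lost it with an estimated correlation (median 0.67, adjusted p = 0.639) and by directional fry (median 0.67, adjusted p = 0.0629). Of 13 lists called, 8 kept their call in those 15 settings and 0 changed sign. The number of lists past the test was 10 to 14 there, 0 with an estimated correlation and 35 by mixed fry, which asks only whether members change in either direction. The trend and robust option does not enter camera. For 155 single genes, 2068 of 2461 values kept direction and side of the threshold, 218 fell short of it, 167 passed it and 8 reversed, of 3 genes. GPAM, at -0.67, was at 0.026 without fluvastatin replicate 2 (-0.71 to 0.026 leaving out 1 array) because another probe was then its brightest; its main probe stood at -0.75 there. The cause of the other 7 was not tested. LYZ, at -0.26, was at 0.10 without control replicate 3 and 0.0085 without fluvastatin replicate 2 (-0.62 to 0.10). COL1A1, at 0.01, was at -0.0099 with all 5 columns, -0.0066 with the authors' values of all 5, -0.023 with cyclic loess, -0.10 without control replicate 3 and -0.19 without fluvastatin replicate 1 (-0.19 to 0.22). Of 155 genes, 73 lost their call without control replicate 1 and 76 without control replicate 3.

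No paired analysis was possible because the independent control and fluvastatin arrays share only replicate number 1, control replicate 2 being a mean of the others. The files give no slides, so the slide block was not run. Detection of 43.0% to 46.9% of probes limits what can be said of dim transcripts.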

Other observations

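The tests of the added control column and of the gap between the fluvastatin arrays were chosen after the results were seen; those of ribosome biogenesis and FOXO genes were written after the first members had been noticed and before the others had been looked at, with 1 exception in the FOXO list. Genes named in this part were chosen after their values were seen. Factors of ribosome biogenesis and RNA polymerase I stood among the large falls, such as RRS1 (log2 fold change -2.53 ± 0.16), the polymerase subunit gene POLR1G (-2.40 ± 0.18), NOC3L (-2.06 ± 0.15) and PNO1 (-2.05 ± 0.16). Of 28 members noticed, 27 fell, which is no test because their values had been seen. A second set of 65 members, written from general knowledge, was then tested: 59 were measured, 36 fell and 0 rose, among them PPAN (-1.37), NLE1 (-1.33), DKC1 (-1.24) and nucleolin NCL (-1.09). Their median was -0.84, below each of 10000 random lists matched on brightness (95% of them between -0.17 and 0.18), and it was -0.81 in both fluvastatin arrays. Camera gave p = 8.86e-17, and p = 0.0208 with an estimated correlation. These values are consistent with a broad fall of ribosome biogenesis transcripts with fluvastatin, which remains a hypothesis; the ribosomal protein genes themselves had 0 of 27 changed.

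Genes known as targets of FOXO transcription factors stood among the rises, such as PDK4 (2.46 ± 0.25), FBXO32 (2.28 ± 0.20), KLF9 (2.20 ± 0.16), TXNIP (1.71 ± 0.16), BMF and TSC22D3. Of 16 members whose values had been seen, 14 rose and 0 fell, which is likewise no test. After a first run of the test, ATG12, whose value had already been seen, was moved out of the further members; with it their median was 0.51 (camera p = 0.00572; p = 0.164 with an estimated correlation). Of the 23 left, 21 were measured, 10 rose and 1 fell: HBP1 (1.58), KLHL24 (1.51), MXI1 (1.35) and CCNG2 (1.42) were higher and GADD45B was at -1.30. By sign alone, 14 of the 21 were positive and 7 negative. The median of 0.60 stood at percentile 99.98 of matched random lists (camera p = 0.00555), but camera with an estimated correlation gave p = 0.133. FOXO activity may be higher with fluvastatin, a hypothesis that the test with an estimated correlation leaves open. The arrays measure no FOXO protein, and other regulators share these targets.

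Probes of AKR1C3 (2.29 ± 0.20) and AKR1C4 (2.70 ± 0.21) also rose. Whether the probes of these genes and of AKR1C2 also bind each other's transcripts was not tested. RN7SK was at 2.23 ± 0.20 at its brighter probe, RNU4-2 at 2.55 ± 0.23 and SNORD3A at 1.84 ± 0.20, all past the threshold. RNU4-1 (-0.02, adjusted p = 0.955), RNU4ATAC (-0.22, adjusted p = 0.658) and VTRNA1-1 (0.83, adjusted p = 0.397) were not.

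The fluvastatin arrays stood apart along the second principal component (24.9 and -33.2, with controls at 2.97 and 5.29), which held 16.4% of the variance. On the first (76.8% of the variance), fluvastatin replicate 1 lay at 57.2 and replicate 2 at 31.8 (controls -44 and -45.1). Of the probes kept, 14% and 14.2% lay at least 2-fold from control replicates 1 and 3 in fluvastatin replicate 1. In fluvastatin replicate 2 the shares were 8.12% and 8.31%. Across the probes kept, replicate 1 thus lay farther from the controls. Replicate 1 was higher in ANGPTL4 (10.65 against 7.75), OASL (8.74 against 6.28) and IL1B (11.24 against 9.47), and replicate 2 in MYB (8.02 against 4.87) and HLA-DRA (11.17 against 9.56). A stronger response of replicate 1 in every gene group would put it farther from the controls in each called list, but by list medians it was farther in 7 and nearer in 6 of 13 (8 and 5 by the median gap per gene), and its gap for the cholesterol list stood at percentile 1.16 of matched random lists. A brightness-dependent array effect would leave the hypoxia list among matched lists, but its gap stood at percentile 100, also after cyclic loess. The hypoxia list was chosen for this after results had been seen, so its percentile is no independent test. Each value compares 2 single arrays, and the labels do not say whether these came from separate cultures. If they did, differences between the cultures, such as density or oxygen, stay open and untested.

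The count of probes changed rose from 3722 to 8991 when control replicate 2 was included. The fits differed only in that column, which also entered the normalization and the filter (22199 probes kept against 21986). Its inclusion therefore gave the whole rise. Another control culture could not give a column equal to the mean of the others in 47231 of 47231 probes. In 20 simulated sets with no change, adding such a mean column raised the share of probes at an unadjusted p under 0.05 from 5.00% to 14.9%, but adjusted calls only from 0 to 0.65 on average (highest 2). In 20 simulated sets with 30% of probes changed, it raised the share of false calls from 3.58% to 15.8%. These sets did not repeat the normalization or the filter. Adjusted calls in them rose 1.60-fold (1.57 to 1.68), from 2970 to 4765 on average. The count in the deposited data rose by more than that, and why the column was deposited in this form is not recorded in the files.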
